A study of Mus musculus with 4 samples.

How the data were processed

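Total RNA of 4TO7 cells was labelled with Cy5 and Universal Mouse Reference RNA with Cy3 on every array, per the labels' protocols, with no dye swap. All 4 arrays were read on 1 slide in 1 scan, so slide and scan could not enter as a block. Per the file headers, Agilent Feature Extraction 9.5.3.1 gave each spot's mean signal and median local background as intensity, a processed intensity corrected for background and dye, and the log10 ratio of processed Cy5 over Cy3. The deposited value table of the authors holds log2 ratios. Set against the scanner values, it was the Feature Extraction log ratio in log2, centred on each probe's median over the 4 arrays, with between 87.3% and 87.8% of values within 0.001. Its column medians were 0.0133 and -0.0172 for the vector arrays and 0.0221 and -0.0149 for the miR-23b/27b/24 arrays, and its direction was Cy5 over Cy3. The program that made it is not given in the sources used here.

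Analysis started from the mean signals and local backgrounds, in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50 on all spots, followed by loess within each array with weight 0 for control spots. Local backgrounds marked as outliers by Feature Extraction, between 1782 and 1976 spots per array in Cy5, were first replaced by the array's median local background. This replacement was not part of the plan, which named normexp without saying how such backgrounds are treated. It was chosen after its own results and those with every background as measured had been seen, and after other planned settings had given counts near the one it led to. The reason was the fit itself. With every background as measured, the fitted Cy5 background mean was -662 on vector replicate 1, where 9 spots had a local background over 200 (the highest at 26398), and -51.2 on vector replicate 2, with 18 such spots, against -12.9 and -8.11 on the miR-23b/27b/24 arrays, which had 0. With the replacement it was between -8.63 and -4.90 on all 4 arrays. Counts from both forms are given.

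Outlier spots and control spots were left out, and spots of a probe were averaged. Of 41174 probes, 22951 were named through an accession, 6659 through the symbol and 3109 through a synonym in a RefSeq table of GRCm38.p6, used for names alone, and 8455 kept the name in the files. Probes well above background in Cy5 on both arrays of at least 1 group were kept (30080), and a gene was represented by its probe with the highest mean intensity. Groups were compared with lmFit and eBayes (2 residual and 2.83 prior degrees of freedom), with Benjamini-Hochberg adjusted p under 0.05. Apart from the replacement, the test, the filter, the gene lists and the rule for named genes were fixed before the data were examined. The test was also run on 20 simulated data sets of 20500 genes with 200 changed genes. It called, in the right direction, 0% of changes of 0.5 in log2 and 3.70% of changes of 1. For changes of 2 and 4 these shares were 76.5% and 97.2%, and 4.71% of the test's calls were false. These rates hold for the simulated data alone. The measured data gave 1929 calls. Their differences between replicates had an SD of 0.413 for the vector arrays and 0.257 for the other group. Whether the rates carry over to them was not tested. The series calls the arrays of a group transfection replicates of a stable line, so the p-values of single genes measure the spread between these.

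Named genes were Psap and Aopep, the 12 largest rises and 12 largest falls among called genes whose arrays did not overlap and that were well above background on all 4 arrays (leaving out clone, RIKEN, predicted and accession names), up to 4 genes per direction with only a bound, and from each list up to 4 called members with the largest change, or the 2 with the smallest p. Some genes that the rule names are not reported here. A bound sets the bright group's mean Cy5 log2 signal, after loess and Aquantile, against the dim group's, taken per array as the higher of the probe's own signal and the lowest signal well above background; where the fold of the log ratio is smaller, it is given instead. Of 971 list entries 921 were measured, and 32 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01. These p-values rest on the spread across genes, treat list members as nearly independent, and can be far too small where members move together. Among the lists that passed, the estimated correlation ran from -0.0325 for growth factor feedback to 0.976 for G2 and M genes. It was 0.845 for S phase, 0.706 for interferon and 0.261 for epithelial genes. Camera with an estimated correlation and fry were alternatives, as were other background, scaling, filter, probe and moderation choices, a replicate block and leaving out each array. With an estimated correlation, camera's test rests on the 2 residual degrees of freedom, so a list was likely to miss whatever its shift. The adjusted p-values given below for that form therefore cannot show that a list did not shift. A test of genes with seed matches in their 3' UTR was planned, and no 3' UTR sequences were used here, so it was not run.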

Results

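Gene expression was measured in 4TO7 cells, a mouse mammary tumour line, that stably carried either the retroviral vector pMSCV-puro alone or the vector with the microRNA cluster miR-23b/27b/24. Each group had 2 arrays, which the series describes as transfection replicates. RNA of the cells was labelled with Cy5 and hybridised against Cy3-labelled Universal Mouse Reference RNA, a mix of 11 mouse cell lines, on a whole-mouse-genome array read in 2 colours. Between 69.9% and 74.8% of the 41174 gene probes were well above background in the Cy5 channel on an array. After filtering, 20500 genes were compared, each by the log2 ratio of cells over reference. Across genes, which are not independent replicates, the log2 ratios correlated at 0.887 between the vector arrays, at 0.952 between the miR-23b/27b/24 arrays and at 0.629 to 0.725 between arrays of different groups. The number of arrays limits the precision of every value below.

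The comparison asked which transcripts differ in cells that overexpress the cluster. The largest rise was that of Esm1, a secreted endothelial proteoglycan, by 7.33 ± 0.20 on the log2 scale (SE, n = 2 arrays per group, limma adjusted p = 0.00152), a 161.3-fold difference; the log2 value was 5.90 with every local background as measured and 8.66 with Feature Extraction signals and loess. Slpi, a secreted protease inhibitor, was 40.3-fold higher, and Ppic, a cyclophilin, 27.9-fold higher. Msln, which encodes the surface protein mesothelin, showed the largest fall, a 40.8-fold difference. Its log2 fold change was -5.35 ± 0.12 (SE, n = 2 arrays per group, limma adjusted p = 0.00152). Over the alternative settings the log2 value of Msln lay between -9.46 and -5.32, and that of Ppic between 4.00 and 7.21. That of Slpi lay between 3.08 and 6.55. Ptpn22, a tyrosine phosphatase of immune cells, was 29.3-fold lower, the tetraspanin Tspan12 25.4-fold lower, the adaptor Grb7 23.1-fold lower and the keratin Krt7 22.5-fold lower. The Esm1 probe lies on chromosome 13 from 110373894 to 110373953 and the Msln probe on chromosome 17 from 23931864 to 23931923, in the mm7 coordinates of the file headers.

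Also among the 12 largest rises were Xlr, Ott, Slxl1, Medag, Scara5, Selenbp1, Fetub and Aspg, with rises between 13.4-fold for Aspg and 29.8-fold for Xlr. Xlr, Ott and Slxl1 belong to X-linked multicopy families of near-identical members and Selenbp1 has a close paralog, so these 4 probes may read more than 1 gene. Among the 12 largest falls were also Ifi44, an interferon-induced gene, Mmp13, a collagenase, Dsp, which encodes the desmosomal protein desmoplakin, the growth factor Bmp7, Endod1, Sorbs2 and the potassium channel gene Kcnk1, with falls between 18.0-fold for Kcnk1 and 22.0-fold for Ifi44. The vector arrays lay apart for Slpi, Ifi44, Tspan12 and Mmp13, whose folds were 93.7, 44.5, 15.4 and 12 without vector replicate 1 and 17.4, 10.8, 42.0 and 32.1 without vector replicate 2. Genes not well above background in one group have only a bound, given as the smaller of the Cy5 channel's bound, which is open to dye bias, and the fold of the ratio to the reference, to which the adjusted p belongs. Lmo1, a transcription cofactor, was at least 20.6-fold lower in the miR-23b/27b/24 cells (adjusted p = 0.00176), Tmem54 at least 15.3-fold, Bspry at least 14.8-fold and the serine protease Tmprss11e at least 14.0-fold. Ecrg4 was at least 10.7-fold higher there (adjusted p = 0.00223), the transcription factor Batf at least 8.26-fold, Papln at least 3.98-fold and Shisa2 at least 3.38-fold. These bounds hold for outlying local backgrounds replaced: with every background as measured, Lmo1, Tmem54, Tmprss11e and Batf had log2 fold changes of -2.88, -2.35, -2.30 and 2.16 and were not called (adjusted p between 0.0657 and 0.113), and Bspry had -3.19 (adjusted p = 0.0477).

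**Figure D1:**
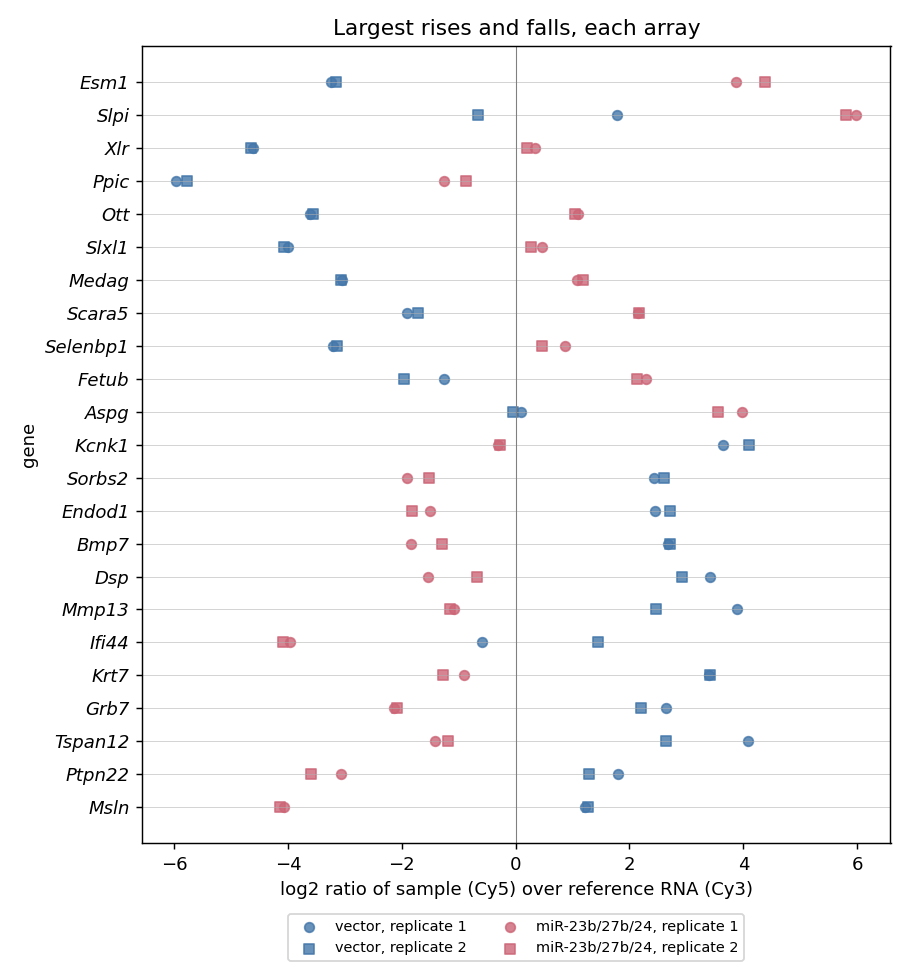
Log2 ratio of cell RNA (Cy5) over reference RNA (Cy3) on the horizontal axis for 11 of the 12 largest rises and the 12 largest falls, 1 gene per row, with 1 point per array (2 vector and 2 miR-23b/27b/24 arrays). In each row the arrays of the groups do not overlap, and the vector arrays lie far apart for Slpi, at 1.78 and -0.66.

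In all, 1929 of the 20500 genes passed an adjusted p of 0.05 in limma, 978 higher and 951 lower in the miR-23b/27b/24 cells, and 1192 of them also differed by at least 2-fold, 577 higher and 615 lower. The arrays of the groups did not overlap for 59.8% of genes, against 33.3% by chance. These counts moved strongly with single arrays and with the background step: leaving out miR-23b/27b/24 replicate 1 or 2 left 214 or 236 genes, leaving out vector replicate 1 gave 4589, median centring in place of loess gave 1263, and a background fit that took every local background as measured gave 635, 267 higher and 368 lower. Of the 122 called genes that the naming rule picked, 52 missed the threshold with every background as measured, and 75 or 76 without miR-23b/27b/24 replicate 1 or 2. The treatment of outlying local backgrounds behind the 1929 genes was chosen after both results had been seen.

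Epithelial genes were lower in the miR-23b/27b/24 cells. Of 33 measured members 18 fell and none rose (27 fell when adjusted over the list alone), with a median log2 fold change of -2.04 (-1.19 over genes well above background in both channels on all arrays). Krt7 was accompanied by Dsp, 19.5-fold lower, by Grhl2, a transcription factor of epithelial cells, 17.1-fold lower, and by St14, the membrane serine protease matriptase, 16.9-fold lower. These folds depended on the fit. Over the alternative settings the log2 fold change lay between -4.91 and -2.16 for Dsp, -5.08 and -2.36 for Grhl2, and -4.91 and -2.48 for St14. The list passed camera with a preset correlation (adjusted p = 1.84e-16), and had an adjusted p = 0.716 with an estimated correlation. Of 33 mesenchymal genes 2 rose and 3 fell, with a median of 0.00 and no shift detected (adjusted p = 0.581). Foxc2 fell by 3.80 ± 0.14 (SE, log2), Twist1 was 7.8-fold lower (13.7-fold or 4.4-fold without miR-23b/27b/24 replicate 1 or 2) and Sparc, a matrix protein, 2.4-fold higher.

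Interferon response genes were lower as well, with 22 of 39 measured members fallen and none risen (32 fell when adjusted over the list alone) and a median log2 fold change of -1.74. Ifi44 was 22.0-fold lower, the antiviral genes Ifit1 and Oasl2 each 8.1-fold lower and Mx2 7.8-fold lower; without vector replicate 1 or 2, Ifi44 was 44.5-fold or 10.8-fold lower, Ifit1 14.2-fold or 4.6-fold, Oasl2 12.4-fold or 5.2-fold and Mx2 14.0-fold or 4.4-fold. The list's median was lower on vector replicate 1 than on vector replicate 2, by a median difference per gene of -0.74. Camera gave an adjusted p = 4.87e-16, and adjusted p = 0.790 with an estimated correlation. Of 35 chemokine and cytokine genes 9 fell and none rose (11 fell and 5 rose when adjusted over the list alone). Il1a, which encodes interleukin 1 alpha, was at least 22.6-fold lower by a probe not well above background in the miR-23b/27b/24 cells. The other Il1a probe had the same sign. Over 18 alternative settings the Il1a log2 fold change lay between -5.91 and -3.49, and 1 setting missed the threshold, so this bound belongs to the fit used here. Ccl20 was 8.5-fold lower (5.5-fold or 13.1-fold without miR-23b/27b/24 replicate 1 or 2), Ccl5 4.5-fold lower and Cxcl10 4.2-fold lower. The log2 fold change of Ccl20 lay between -3.71 and -1.45 over the alternative settings. The shift of that list (median -0.12, adjusted p = 0.0410) had an adjusted p = 0.790 with an estimated correlation, and missed the threshold without vector replicate 1 (adjusted p = 0.508) and with the authors' deposited values (median -0.33, adjusted p = 0.0794). Its median was -0.40 without vector replicate 2, and -0.195 or -0.316 without miR-23b/27b/24 replicate 1 or 2, and -0.48 with every local background as measured (adjusted p = 0.131).

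S-phase genes were higher in the miR-23b/27b/24 cells, where 8 of 35 measured members rose and none fell (24 rose when adjusted over the list alone), with a median log2 fold change of 1.13. They included Ccne1, a cyclin that acts at the entry into S phase, 4.0-fold higher, the replication clamp gene Pcna, 3.9-fold higher, the origin licensing factor Cdc6, 3.5-fold higher, and E2f1, 3.0-fold higher. No single one of the 36 genes of the G2 and M phases passed, although 34 had a positive log2 fold change (median 0.76). Nuf2 differed by 1.62 ± 0.41 (SE, log2, adjusted p = 0.0792) and Bub1 by 1.38 ± 0.42 (SE, log2, adjusted p = 0.117). Both lists also differed between the vector arrays, with replicate 1 above replicate 2 by a median of 0.80 for S phase and 1.10 for G2 and M. Without vector replicate 1 the median log2 fold change of the G2 and M list was 1.32, and without vector replicate 2 it was 0.24 (0.67 for S phase). Camera gave adjusted p = 3.32e-11 for S phase and adjusted p = 6.31e-06 for G2 and M, and each had an adjusted p = 0.790 with an estimated correlation.

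Ribosomal protein genes were lower by a median log2 fold change of -0.53, with 9 of 50 fallen and none risen (22 fell when adjusted over the list alone). Rps23 was 2.3-fold lower, and Rps28 and Rpl36 each 2.0-fold lower. Rps12 was 2.9-fold lower by its brightest probe, and its other probe had the opposite sign. Camera gave an adjusted p = 8.04e-11, and adjusted p = 0.790 with an estimated correlation. Cholesterol synthesis genes were higher (median 0.37), with 4 of 25 risen and none fallen (9 rose when adjusted over the list alone). Hsd17b7 was 3.7-fold higher, Sqle, an enzyme of sterol synthesis, 2.5-fold higher, and Insig1, a regulator of sterol synthesis, 2.3-fold higher. This list had a camera adjusted p = 0.000684, adjusted p = 0.790 with an estimated correlation, and missed the threshold without vector replicate 2 (adjusted p = 0.103), while its median was 0.61 without vector replicate 1.

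A list that joins immediate early genes with heat-shock and stress genes was higher in the miR-23b/27b/24 cells, with 5 of 21 risen and 1 fallen (9 and 2 when adjusted over the list alone) and a median log2 fold change of 0.55. The transcription factors Egr2, Egr1 and Fos were 11.9-fold, 8.6-fold and 3.1-fold higher, and Gadd45b, a stress-response gene, was 5.5-fold lower. Over the alternative settings the log2 fold change lay between 2.73 and 5.66 for Egr2, 2.78 and 7.64 for Egr1, and 1.02 and 2.95 for Fos. Genes of growth factor feedback, a list that shares Egr1, Fos, Dusp1 and Ier3 with the previous one, had 6 of 25 risen and 2 fallen (11 and 4 when adjusted over the list alone) and a median of 0.60. The 2 that fell were Myc, 3.0-fold lower, and Hbegf, 2.0-fold lower. Camera gave an adjusted p = 0.00482 for the list of immediate early and heat-shock genes and an adjusted p = 0.00632 for the feedback list, and both had an adjusted p = 0.716 with an estimated correlation. Of 28 genes regulated by p53, 5 fell and 1 rose (8 and 2 when adjusted over the list alone), with a median of -0.35. Perp, a desmosomal gene, was 10.1-fold lower (15.4-fold or 6.6-fold without vector replicate 1 or 2), Ddit4 5.9-fold lower and Ei24 2.7-fold lower, while Cdkn1a, the cell cycle inhibitor p21, was 2.4-fold higher. That list had a camera adjusted p = 0.00998 and an adjusted p = 0.716 with an estimated correlation.

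**Figure D2:**
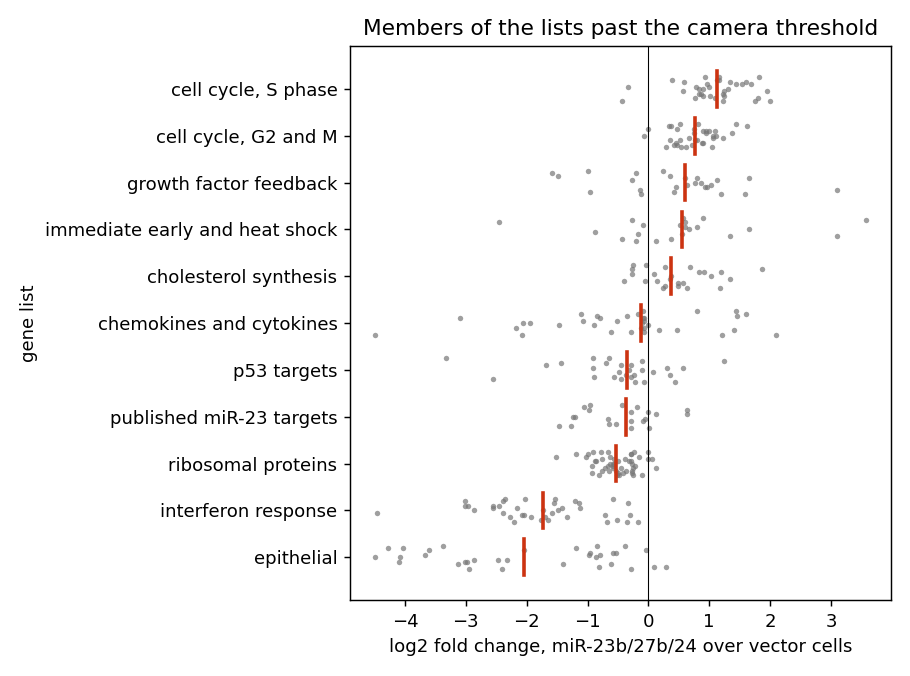
Log2 fold change (miR-23b/27b/24 over vector cells, from the means of 2 arrays each) of each measured gene, drawn as a grey point, in the 11 lists that passed camera with a preset correlation, with the list's median as a red bar. Medians run from -2.04 for epithelial genes to 1.13 for S-phase genes, and vertical scatter within a row only separates points.

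Published targets of the cluster's microRNAs, listed from earlier literature, were compared next. Of 22 miR-23 targets 6 fell and none rose (10 fell and 1 rose when adjusted over the list alone), with a median log2 fold change of -0.36. Prodh, which encodes proline dehydrogenase, was 2.4-fold lower, Tgfbr2, a receptor for TGF-beta, 2.3-fold lower, Tab3, an adaptor of the kinase TAK1, 2.1-fold lower, and the kinase gene Ptk2b 2.0-fold lower. The miR-23 list had a camera adjusted p = 0.00190 and an adjusted p = 0.790 with an estimated correlation, and its median was -0.23 with the mean of each gene's probes. Of 25 miR-27 targets 3 rose and 4 fell (median 0.11, and 0.01 without vector replicate 2, adjusted p = 0.628), among them Notch1, 4.7-fold higher, Abca1, a cholesterol exporter, 3.9-fold higher, Mmp13, 19.7-fold lower, and St14, 16.9-fold lower. Of 26 miR-24 targets 3 rose and 1 fell (median 0.41, adjusted p = 0.107; adjusted p = 0.0134 without vector replicate 1; median 0.22, adjusted p = 0.211, without vector replicate 2), among them Fen1, a flap endonuclease, 2.3-fold higher, Gata2, 2.0-fold higher, and Myc, 3.0-fold lower.

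Prosaposin, the lysosomal precursor protein followed up in work on this cluster, showed no detected difference. Psap had log2 ratios of 1.48 and 1.24 on the vector arrays and of 1.71 and 0.84 on the miR-23b/27b/24 arrays, a log2 fold change of -0.09 ± 0.31 (SE, n = 2 arrays per group, 95% interval -0.90 to 0.72, limma adjusted p = 0.894). Its other probe gave 0.17. The brighter Psap probe lies on chromosome 10 from 59820272 to 59820331 in mm7. The interval leaves room for a change of either sign. Aopep, the gene that hosts the cluster, differed by -0.63 ± 0.28 (SE, n = 2 arrays per group, limma adjusted p = 0.228), by -0.250 or -1.004 without vector replicate 1 or 2, and another probe of it gave -0.04. Its probes may lie outside the expressed insert, and mature microRNAs are not measured on this array, so the level of the cluster itself was not checked here.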

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

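The replacement of outlying local backgrounds and the removal of reference signal were chosen after seeing the data; every background as measured was the form run first, and the rest were planned. With every local background as measured, 635 genes passed, and 540 at 2-fold; 577 of the 1929 genes were called the same way, and 52 of 122 named genes missed the threshold, against 75 and 76 without miR-23b/27b/24 replicate 1 and 2, 82 with every background as measured and reference signal removed, and at most 20 in any other setting; the fold moved by over 1.5 times for 29 with every background as measured, 33 with Feature Extraction signals and loess and 39 with reference signal removed. The first explanation tried for that fit, Cy5 signal proportional to the reference, was removed from those values and left 270 genes, all at 2-fold; removed after outlying backgrounds had been replaced, it left 1700 and 1334. With both, every background as measured and the removal, the median of p53 genes was -0.61 and that of miR-23 targets -0.62. Feature Extraction signals with loess, its log ratio, the authors' table, no background correction and Cy5 alone gave between 1869 and 2060 genes, and median centring gave 1263. Aquantile leaves the ratios as they are and tests nothing. Leaving out 1 array gave between 214 and 4589 genes, and between 214 and 2143 at 2-fold: 214 without miR-23b/27b/24 replicate 1, 236 without replicate 2, 4589 without vector replicate 1 and 2725 without vector replicate 2. With 1 array left in a group, that array is assumed to vary like the other group's. Apart from Psap, no called named gene and none of the 11 lists turned its direction under any setting. Of the 11 lists 0 passed with an estimated correlation and 0 in fry. Camera with an estimated correlation rests on the 2 residual degrees of freedom, so its misses do not decide whether a list shifted. The feedback list missed too, although its estimated correlation was -0.0325. In fry, epithelial genes and the lists of feedback and of immediate early and heat-shock genes each had an adjusted p = 0.0504. The chemokine list missed the threshold in 9 other settings and cholesterol synthesis in 1. The log2 fold change of Psap, not called under any setting, was 0.04 with the mean of its probes, and between -0.52 and 0.35 with 1 array left out (0.04 without vector replicate 1, 0.35 without miR-23b/27b/24 replicate 2); the cause was not tested. A replicate block gave 1740 genes, and deviations of same-numbered arrays correlated at 0.0465 across genes, so no shared deviation of such arrays was seen. With 1 difference per group, this cannot show whether same-numbered arrays were handled together. Slide and scan as a block, and every setting for 3' UTR seed matches, were not run. Probes not well above background have only bounds.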

Other observations

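Lists not described above had no shift detected by camera with the settings used above, and several of them held single large changes. In guidance genes 3 of 31 rose and 4 fell (adjusted p = 0.468), with Sema3b 7.0-fold higher and Sema3e 3.1-fold lower. In Wnt and Notch genes 2 of 28 rose and 3 fell (adjusted p = 0.697), with Notum, a Wnt-inactivating enzyme, 3.4-fold higher. Jag2, a Notch ligand not well above background in the miR-23b/27b/24 cells, was at least 5.09-fold lower in the fit used here. Over 18 alternative settings the Jag2 log2 fold change lay between -4.63 and -1.90, and 2 settings missed the threshold. Among matrix and adhesion genes 3 of 45 rose and 7 fell (adjusted p = 0.260), with the laminin genes Lama4 11.1-fold higher (well above background on 1 of 2 vector arrays, and 19.1-fold or 6.5-fold without miR-23b/27b/24 replicate 1 or 2) and Lamb3 8.4-fold lower, and among matrix proteases 2 of 32 rose and 4 fell (adjusted p = 0.203), with Mmp9 4.9-fold lower and Adam19 3.1-fold lower. Of 41 TGF-beta pathway genes 2 rose and 6 fell (adjusted p = 0.628), with the co-receptor gene Eng 5.0-fold lower, and of 25 TGF-beta response genes 3 rose and 4 fell (adjusted p = 0.924; the median was -0.15 and the mean 0.06), with Ccn2 3.0-fold higher. Of 27 metastasis suppressors 1 rose and 6 fell (adjusted p = 0.394), with Akap12 14.9-fold lower and Cdh1, which encodes E-cadherin, 7.7-fold lower (4.8-fold or 12.5-fold without miR-23b/27b/24 replicate 1 or 2).

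Among endoplasmic reticulum stress genes 5 of 32 rose and 2 fell (adjusted p = 0.255), with the chaperone genes Pdia6 3.7-fold and Calr 3.0-fold higher. Of 48 lysosomal genes none rose and 5 fell (adjusted p = 0.628), among them the cathepsin gene Ctsc, 8.6-fold lower. Of 28 hypoxia and glycolysis genes 1 rose and 2 fell (adjusted p = 0.467), with Ndrg1 6.2-fold lower. Fatty acid genes (adjusted p = 0.628) had 2 of 36 risen and 1 fallen, with Fads1 4.2-fold lower, and oxidative phosphorylation genes (adjusted p = 0.912) had 1 of 46 fallen, Ndufs7, 1.6-fold lower. Among markers of other cell types, luminal mammary genes had 1 of 10 risen and 3 fallen (adjusted p = 0.225), with the milk protein gene Csn3 10.9-fold higher, Krt19 16.3-fold lower and the oestrogen receptor gene Esr1 5.6-fold lower. Basal markers had 2 of 12 risen and 1 fallen (adjusted p = 0.628), with Mylk 3.9-fold higher and Krt14 2.4-fold lower. Acta2 was 1.9-fold higher by its brightest probe, and its 3 other probes had the opposite sign. Fibroblast markers had 2 of 11 risen (adjusted p = 0.177), Pi16, 5.9-fold higher, and Col6a3, 2.9-fold higher. Macrophage markers had 1 of 15 fallen (adjusted p = 0.225), Cd68, 3.2-fold lower. No endothelial marker of 8 (adjusted p = 0.260) and no lymphocyte marker of 11 (adjusted p = 0.919) passed. Some of these lists passed under another setting. Without vector replicate 2, matrix proteases, endoplasmic reticulum stress genes, hypoxia and glycolysis genes and fibroblast markers passed, with medians of -0.29, 0.51, -0.37 and 0.21. Without vector replicate 1 these medians were 0.01, -0.04, 0.205 and 0.01 in the same order. The stress and the hypoxia lists thus turned sign with the vector array left out. Fibroblast markers also passed without miR-23b/27b/24 replicate 2, with a median of 0.08. Macrophage markers were lower with every local background as measured (median -0.83, adjusted p = 0.00282, and 0.0126 after removal of reference signal as well), and luminal mammary genes among genes well above background in both channels on all arrays (adjusted p = 0.0429).

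The tests below were chosen after their results or earlier forms of them had been seen, except the one on GC content and the one on interferon genes.

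The first pattern is the number and size of the differences between the groups. Repression by the microRNAs stays open: genes that fell held a 7-base seed match in their 60-base probe in 17 of 951 cases, against 440 of 18571 genes not called (odds ratio 0.750, 95% interval 0.431 to 1.22, two-sided Fisher's exact p = 0.273), and most of each 3' UTR was not searched. Over all genes, no downward shift was detected for those with a match in the probe. Their mean log2 fold changes lay at percentiles 38.5, 47.0 and 69.2 among 7-mers of like frequency for miR-23b, miR-27b and miR-24. The 95% intervals of the difference of means were -0.094 to 0.070, -0.088 to 0.088 and -0.069 to 0.126. They leave room for a small shift of either sign. After removal of signal proportional to the reference, 89.4% of the 2-fold calls stayed called at 2-fold. This share decides little, because that signal was estimated at a like 9.92% to 11.7% of Cy3 on all arrays. Removing it mainly widens differences: genes at 2-fold or more, at any p, rose from 1679 to 2329. With every background as measured as well, 20.7% of the 2-fold calls stayed, a setting that changes 2 steps together. Of the 1177 calls at 2-fold or more with a position, 94.5% stayed at 2-fold or more once the median of their 20 Mb window was removed. The largest window median was 0.27 in log2, so only calls near 2-fold could drop out. The test therefore shows only that shifts of whole windows were small next to most of these calls. It cannot decide on gains or losses of shorter segments, which a window median does not capture. A difference between the cell populations that arose apart from the cluster, such as in their derivation, remains a possible explanation. The series calls a group's arrays transfection replicates, and the labels do not say whether these were derived separately. Such a difference therefore cannot be separated here from the cluster's effect.

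The second pattern is a shift of neighbouring genes. Over 138 windows of 20 Mb, the spread of the median log2 fold change was 2.42 times that of genes shuffled over positions (permutation test over gene positions, p = 1e-04, the smallest that 10000 shuffles can give). The largest median was 0.27 on chromosome 2 from 140000001 to 160000000 (211 genes, mm7), followed by 0.25 in each of the adjoining windows of chromosome X from 160000001 to 180000000 (22 genes) and from 140000001 to 160000000 (93 genes). On chromosome 2 the windows that follow had medians of 0.22 (from 160000001, 178 genes) and 0.18 (from 180000001, 59 genes). The window before them all, from 120000001, had 0.0456 (217 genes). The GC content of the probes is argued against, as the spread stayed at 2.43 times the shuffled one after adjustment for GC and intensity. Gains or losses of chromosome segments that differ between the cell populations are a candidate explanation, as is shared regulation of neighbouring genes, which was not tested.

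The third pattern appeared with every local background as measured: over 252 probes with a mean log2 ratio under -3 on the miR-23b/27b/24 arrays, a choice that itself favours higher vector values, vector replicate 1 lay above the miR-23b/27b/24 arrays by a median of 1.93 in log2, and vector replicate 2 by 0.506. Among them Xist was at -3.03 and -4.91 on the vector arrays and at -5.31 and -5.43 on the others. Outlying local backgrounds in the normexp fit are a candidate explanation, since replacing them left an excess of 0.105 on vector replicate 1 and of 0.174 on vector replicate 2 over the same probes. Expression of these genes in vector cells is argued against by an excess of 0.214 in Feature Extraction's own log ratio. The first explanation tried, a Cy5 component proportional to the reference, is argued against by an excess of 0.0541 in the background-subtracted ratio before normexp and loess.

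Interferon response genes were higher on vector replicate 2 than on vector replicate 1, and without vector replicate 2 the list's median log2 fold change was -1.34, so that array alone did not account for the difference.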
